A study of Mus musculus with 24 samples.

How the data were processed

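The series measured RNA of mouse cells sorted from embryoid bodies, which are aggregates of differentiating embryonic stem cells. Cells with and without Flk1 on their surface were collected at 84 h, 95 h and 8 d, and 4 samples of each of the 6 groups were hybridised, 1 per array, to 24 two-colour Agilent mouse development arrays. Per the labels, sample RNA was isolated with Qiagen RNeasy and carried Cy5, and the common reference, RNA of homogenised whole pups isolated with a guanidinium method, carried Cy3. Both were amplified, and no array had the dyes exchanged, so an effect of the dye on a probe is the same on all 24 arrays and drops out of differences between groups. The labels number the samples of a group 1 to 4 but do not say that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

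The deposited values are given per probe and array on a logarithmic scale, handled here as a log2 ratio of sample over reference. The sources used here give no log base, direction, feature extraction, background correction or normalization within arrays. The direction was checked with 2 lists fixed before the data were examined. Of 15 measured genes of newborn pup tissues 13 lay below 0, with a median of -1.75 over all arrays, at percentile 0 of 10000 random lists of that size. All 15 measured embryonic stem cell genes lay above 0, with a median of 1.00 at percentile 100. Values were therefore read as Cy5 over Cy3. With another log base every difference would be multiplied by 1 common factor, with the same signs, calls and p-values.

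The table held 20280 probes with values from -6.42 to 5.33 and no missing value. Each array had a mean of 0 as deposited, a scaling seen from the values and not given in the sources used here. Of the probes, 11813 had 1 gene in the platform annotation, 559 had several and 7908 had none listed, so the last 2 kinds stayed unnamed. The Entrez identifiers of 11782 probes were found in the gene table, and no symbol changed. Probes of 1 gene were averaged, which concerned 2180 genes, leaving 8973 named genes and 8467 unnamed probes, 17440 features in all. For 11 genes, separate probes were called in opposite directions at 84 h, and for 0 at 95 h and 8 d. The largest deviation of an array median from their overall median of 0.0879 was 0.109. This exceeded the tolerance of 0.1 set before the data were examined, so each array's median was set to 0. The spread of values per array (SD) ran from 0.56 to 1.01. For arrays, their number (4 per group) limits the precision.

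Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and data.table (version 1.17.8), and figures used Python 3.11.15 with matplotlib 3.10.9. All 24 arrays entered 1 fit with a mean per group and no covariate, which gave 18 residual and 3.41 prior degrees of freedom. Flk1+ was compared with Flk1- at each time, and consecutive times were compared within each sort. The change of the Flk1+ minus Flk1- difference between consecutive times was tested as an interaction. P-values were adjusted by Benjamini-Hochberg over the 17440 features, and a feature was called at an adjusted p under 0.05 with no fold minimum. Errors printed after a difference are standard errors (SE) from this fit, and those after a group mean are SDs of 4 arrays.

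The labels of the sort, the comparisons, the tests, the lists, the rule for named genes and most alternatives were set before the data were examined. The 22 tested lists were endothelial; hemangioblast and early hematopoietic regulators; erythroid; leukocyte and platelet; primitive streak and nascent mesoderm; lateral plate mesoderm; cardiac contractile; smooth muscle and fibroblast; pluripotency; visceral and definitive endoderm; neural; Wnt ligands and receptors; Wnt intracellular components; secreted Wnt inhibitors; Wnt target genes; Notch; BMP and TGF-beta; VEGF, angiopoietin, PDGF and FGF; basement membrane and matrix; cell cycle; immediate early and heat shock; and hypoxia and glycolysis. Lists were tested with limma's cameraPR at a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with camera and an estimated correlation. The median difference of a list describes its members and can differ in sign from the test, which weighs all of them.

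The rule for named genes took Kdr, the gene of the sort, in every case. For Flk1+ against Flk1- it took the 8 largest positive and 8 largest negative differences among called genes with no overlap between the arrays compared, and up to 4 called members of each list. For times and interactions it took 4 and 4, and up to 2 called members per list. Any called member of the 4 Wnt lists could be named, as could uncalled members with their values. The genes printed are a part of those the rule gave, picked after values and stability were seen, and they lean towards stable ones. Of all genes of the rule at 84 h 76 were named and 54 were kept without 3 arrays that stood apart, 41 when only the 8 arrays compared were fitted and 59 after quantile normalization. These 4 counts were 51, 51, 34 and 47 at 95 h and 26, 26, 25 and 24 at 8 d. For 95 h against 84 h they were 49, 22, 0 and 27 in Flk1+ cells and 30, 27, 9 and 19 in Flk1- cells. For 8 d against 95 h they were 45, 45, 45 and 44 in Flk1+ cells and 44, 44, 43 and 44 in Flk1- cells. For the interaction between 8 d and 95 h they were 19, 19, 18 and 17.

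The fit was tested on simulated data of 17440 features with 200 changed. With 1 spread for all groups, unchanged features made up 6.4% of calls at 84 h, 6.0% at 95 h and 5.1% at 8 d. With each group's own spread these shares were 67.2%, 56.2% and 2.0%, because 1 pooled spread understated that of the wider groups. Unchanged features made up 74.8% of calls for Flk1+ cells at 95 h against 84 h, 21.1% for Flk1+ cells at 8 d against 95 h, 31.0% and 30.4% for the same 2 steps in Flk1- cells, and 51.2% and 18.5% for the earlier and the later interaction. Fits of only the arrays compared brought these shares to 12.7% at 84 h, 8.3% at 95 h, 7.4% at 8 d and 14.7% for Flk1+ cells at 95 h against 84 h. Differences of 1 on the log2 scale were recovered in 89.6%, 94.0% and 80.6% of simulated genes at 84 h, 95 h and 8 d with all arrays. With only the arrays compared these shares were 56.7%, 58.2% and 95.5%. Counts from the arrays compared are therefore printed beside the counts at 84 h and 95 h.

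Whether equal numbers pair samples was checked from the correlation of deviations from the group means. At 95 h the correlations of the 4 same-numbered pairs were 0.142, 0.408, 0.417 and 0.107, and at 8 d they were 0.293, 0.357, 0.437 and 0.146. All exceeded 0.1, so these samples count as paired by this check, from the data and not the labels. The fit itself has no block. Some of the calls and counts changed by the number as a block within time are given.

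The alternatives fixed at that time were the values as deposited, quantile normalization, a fold minimum, fits of only the arrays compared, the replicate number as a block, array weights, a robust fit, the probe with the largest SD per gene, another minimum of values per group, an estimated correlation for lists, and each array left out in turn. Settings without 2 Flk1+ arrays of 84 h (numbers 2 and 4), without these and Flk1- array 4 of 84 h, without both 95 h arrays numbered 2, and without all 5 were added after seeing the data. The largest shift of the median over all features between these scalings was 0.048, for the deposited values at 84 h.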

Results

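RNA of cells sorted from mouse embryoid bodies was compared with a common whole-pup RNA reference on 24 two-colour arrays. The sort separated cells with Flk1 on their surface (Flk1+), the receptor for VEGF encoded by Kdr, from cells without it (Flk1-). Each sort was sampled 4 times at 84 h, 95 h and 8 d. The study's title names Wnt signalling in the commitment of embryonic stem cells to endothelium, and the comparisons describe which genes differed between the sorts at each time and between times within a sort. Differences are on the log2 scale as read from the deposited values, whose log base the sources used here do not state, and each rests on 4 arrays per group.

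Replicate arrays of a group resembled each other most at 8 d, with correlations over all features from 0.919 to 0.954 in Flk1+ cells and from 0.929 to 0.958 in Flk1- cells. At 95 h the correlations ran from 0.754 to 0.859 in Flk1+ and from 0.666 to 0.901 in Flk1- cells. At 84 h they ran from 0.583 to 0.933 in Flk1+ and from 0.877 to 0.967 in Flk1- cells. The first 2 principal components held 31.2% and 22.1% of the variance. Flk1+ arrays 2 and 4 of 84 h lay apart on both, at 63.6 and 60.6 on the first and -61.8 and -51.7 on the second, and had the widest values (SD 1.01 and 1.00). Flk1- array 4 of 84 h lay between these and its own group, at 24.1 on the first component. Counts without these 3 arrays, chosen after seeing the data, are given with the counts of called features.

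**Figure D1:**
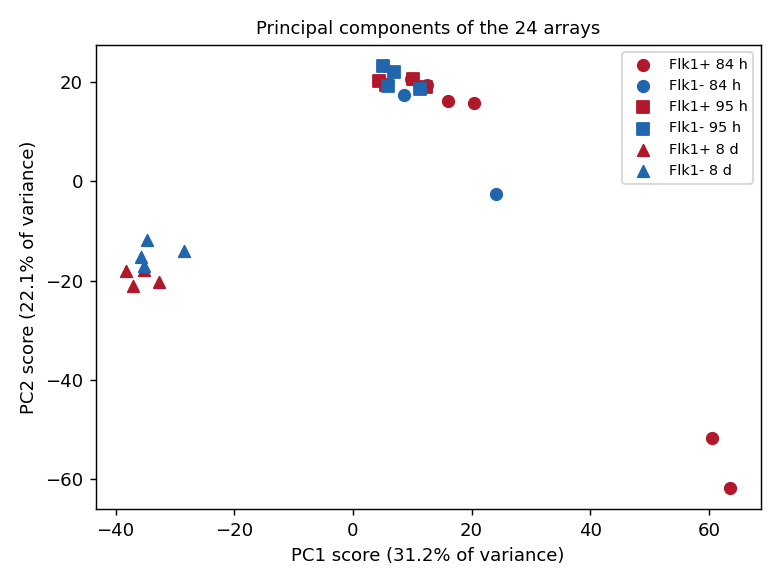
First principal component of the 24 arrays (31.2% of the variance, horizontal axis) against the second (22.1%, vertical axis), 1 point per array, coloured by sort and time. The 8 d arrays lie on the left, and Flk1+ arrays 2 and 4 of 84 h lie apart at 63.6 and 60.6 on the first component.

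Kdr, the gene of the sort, was higher in Flk1+ than in Flk1- cells at each time. Its log2 ratio to the reference was 0.98 ± 0.79 (SD, n = 4) in Flk1+ and -0.92 ± 0.15 in Flk1- cells at 84 h, a difference of 1.91 (SE 0.23, adjusted p = 1.39e-05) or 3.75-fold. At 95 h the means were 1.85 ± 0.11 and -1.08 ± 0.15, a difference of 2.93 (SE 0.23, adjusted p = 1e-07) or 7.61-fold. At 8 d they were 1.58 ± 0.21 and -0.31 ± 0.04, a difference of 1.89 (SE 0.23, adjusted p = 0.000155) or 3.72-fold. The 4 Flk1+ arrays of 84 h gave 1.80, 0.04, 1.43 and 0.67, and the 2 low values belonged to arrays 2 and 4, which stood apart. The gain of the difference from 84 h to 95 h was 1.02 (SE 0.33, adjusted p = 0.278) and its change from 95 h to 8 d was -1.03 (adjusted p = 0.273). The first fell to 0.44 without the 3 arrays that stood apart (adjusted p = 0.362) and to 0.508 with array weights, and the second passed without these arrays (adjusted p = 0.00119), from only the arrays compared (adjusted p = 0.00243) and with array weights (adjusted p = 0.0061). Kdr in Flk1+ cells was higher at 95 h than at 84 h by 0.86 (adjusted p = 0.0165), with arrays that overlapped. This was 0.23 and not called without the 3 arrays (adjusted p = 0.321), and also not called without 84 h array 2 (0.55) or 4 (0.76), with array weights (0.36) or from only the arrays compared (adjusted p = 0.265). In Flk1- cells Kdr was higher at 8 d than at 95 h by 0.77 (adjusted p = 0.0248). That call ended without array 1, 3 or 4 of 8 d (0.77, 0.76 and 0.75), without array 1 of 95 h (0.69) and after quantile normalization (0.585, adjusted p = 0.0822). Array 1 of Flk1- cells at 95 h and array 4 of Flk1+ cells at 8 d lay apart from the other 3 of their groups for Kdr.

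**Figure D2:**
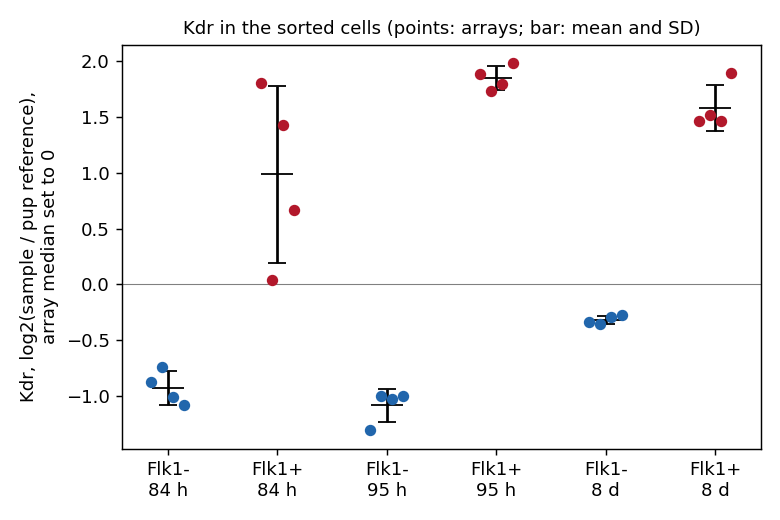
Log2 ratio of Kdr to the pup reference (vertical axis) for Flk1- and Flk1+ cells at 84 h, 95 h and 8 d, with 1 point per array and bars for the mean and SD of 4 arrays. Flk1+ means are 0.98, 1.85 and 1.58 and Flk1- means are -0.92, -1.08 and -0.31.

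At 84 h Flk1+ cells held more RNA of regulators of early and lateral mesoderm than Flk1- cells. Prdm6, a transcriptional repressor of vascular smooth muscle, was 3.28 (SE 0.28) higher, Tbx3, a T-box factor, 2.37 (SE 0.18) higher, and Gata3 2.00 (SE 0.22) higher. Hand1 rose by 1.71 (SE 0.23), the homeobox gene Msx2 by 1.35 (SE 0.18) and the growth factor gene Bmp4 by 1.24 (SE 0.16). Of 16 measured lateral plate mesoderm genes 7 were higher, 0 lower and 9 not called (8 higher and 1 lower when adjusted over the list alone), with a median of 0.45 and a list test at adjusted p = 3.23e-08. Among 14 genes of the primitive streak and nascent mesoderm 6 were higher, 1 lower and 7 not called (8 and 1 adjusted over the list alone), with a median of 0.39 and adjusted p = 0.000784. Snai1, a repressor of E-cadherin, rose by 1.56 (SE 0.20), and Mesp1, a factor of early cardiovascular mesoderm, by 1.49 (SE 0.28), a call that ended when only the 8 arrays compared were fitted. Estimated correlations kept both lists, at adjusted p = 0.00728 and adjusted p = 0.0299. Without the 3 arrays that stood apart their medians were 0.47 and 0.31, and the streak median was 0.22 after quantile normalization.

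Flk1- cells at 84 h held more RNA of pluripotency genes as a list and of some epithelial and endoderm genes. Sox2, a core factor of pluripotent cells, was lower in Flk1+ cells at -3.56 (SE 0.37), Lefty1, an inhibitor of Nodal signalling, at -2.28 (SE 0.17) and the Krüppel-like factor gene Klf2 at -1.97 (SE 0.20). Of 26 pluripotency genes 1 was higher, 13 lower and 12 not called (2 and 15 adjusted over the list alone), with a median of -0.54 and adjusted p = 8.14e-08, or adjusted p = 0.00728 with an estimated correlation. The 1 higher member was Tbx3, which the lateral plate list also holds. Cdh1, which encodes the epithelial adhesion protein E-cadherin, was lower at -2.54 (SE 0.34), Epcam at -2.17 (SE 0.29) and Foxa2, a factor of endoderm and node, at -1.95 (SE 0.20). Of 19 visceral and definitive endoderm genes 3 were higher, 6 lower and 10 not called (3 and 7 adjusted over the list alone), with a median of -0.30 and adjusted p = 0.0101, which became adjusted p = 0.0732 with an estimated correlation. After quantile normalization the endoderm median was 0.075 and the test gave adjusted p = 0.0518. Tpd52, at -3.05 (SE 0.15), and Rpl39l, at -2.87 (SE 0.18), were the other large differences towards Flk1- cells.

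Genes of glycolysis and the response to low oxygen were lower in Flk1+ cells at 84 h. Of 21 measured members 0 were higher, 12 lower and 9 not called (0 and 13 adjusted over the list alone), with a median of -0.66 and adjusted p = 5.74e-09, or adjusted p = 0.0102 with an estimated correlation. Ddit4 was lower at -1.64 (SE 0.23), Pdk1 at -1.54 (SE 0.18) and Ero1a at -1.20 (SE 0.21). Without the 3 arrays that stood apart the median was -0.38, and after quantile normalization -0.41. Of 34 cell cycle genes 1 was higher, 6 lower and 27 not called (1 and 13 adjusted over the list alone), with a median of -0.36 and adjusted p = 0.00589, or adjusted p = 0.446 with an estimated correlation. The cell cycle median became 0.025 without Flk1+ arrays 2 and 4, and leaving out array 2 (-0.185, adjusted p = 0.085) or array 4 (-0.178, adjusted p = 0.0505) alone ended the call. Of 14 immediate early and heat shock genes 0 were higher, 4 lower and 10 not called (0 and 5 adjusted over the list alone), at adjusted p = 0.00202 or adjusted p = 0.116 with an estimated correlation.

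Endothelial and blood genes did not pass as lists at 84 h. Of 28 endothelial genes 3 were higher, 2 lower and 23 not called (3 and 2 adjusted over the list alone), with a median of 0.021 and adjusted p = 0.149. Quantile normalization was the 1 setting in which this list passed, towards Flk1+ cells with a median of 0.156 and adjusted p = 0.000347, and the other settings gave adjusted p = 0.0807 to adjusted p = 0.579. The higher ones included Aplnr at 1.23 (SE 0.16) and Nrp1, a coreceptor for VEGF, at 1.21 (SE 0.11). Nrp1 gave 2.10 from the probe with the largest SD. Among 9 hemangioblast and early hematopoietic regulators 0 were higher, 1 lower and 8 not called (2 and 3 adjusted over the list alone), with a median of 0.083, a mean of -0.16 and adjusted p = 0.647. The lower one was Kit at -1.38 (SE 0.22), which was -0.91 without the 3 arrays that stood apart. Of 13 erythroid genes 0 were called higher or lower by limma (adjusted p = 0.955). Of 11 leukocyte and platelet genes 0 were higher and 2 lower (adjusted p = 0.4), and without the 3 arrays that stood apart this list passed at adjusted p = 0.00747 with a median of -0.33.

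Signalling lists at 84 h had called members on both sides. Of 29 BMP and TGF-beta genes 8 were higher, 1 lower and 20 not called (9 and 2 adjusted over the list alone), with a median of 0.077 and adjusted p = 0.0419, or adjusted p = 0.117 with an estimated correlation. Of 27 genes for VEGF, angiopoietin, PDGF and FGF signalling 5 were higher, 3 lower and 19 not called (7 and 4 adjusted over the list alone), at adjusted p = 0.0364 or adjusted p = 0.221 with an estimated correlation. Fgf10, a growth factor of mesoderm, rose by 1.64 (SE 0.19) among them. After quantile normalization the BMP list had a median of 0.16 and the VEGF list one of 0.12. Of 19 Notch genes 3 were higher, 1 lower and 15 not called (adjusted p = 0.157), and the receptor gene Notch1 rose by 1.22 (SE 0.20). The Notch list passed without Flk1+ array 4 (adjusted p = 0.0305). The BMP list also lost its call without Flk1+ array 1 (adjusted p = 0.21), Flk1+ array 3 (adjusted p = 0.133), Flk1- array 3 (adjusted p = 0.0518) or Flk1- array 4 (adjusted p = 0.0642). The VEGF list lost its call without Flk1+ array 1 (adjusted p = 0.0535), Flk1+ array 3 (adjusted p = 0.0608), Flk1- array 2 (adjusted p = 0.0571) or Flk1- array 3 (adjusted p = 0.056). With the probe of the largest SD they gave adjusted p = 0.159 and adjusted p = 0.126, with the block within time adjusted p = 0.0781 and adjusted p = 0.0553, and the BMP list as deposited adjusted p = 0.0528.

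Lists of other tissues gave few calls at 84 h. Of 22 cardiac contractile genes 1 was higher and 1 lower (adjusted p = 0.865), the lower one being Tnni3, cardiac troponin I, at -0.84 (SE 0.11), or -0.38 after quantile normalization. Of 21 smooth muscle and fibroblast genes 2 were higher and 1 lower (adjusted p = 0.17), with the matrix gene Fbln2 at 1.25 (SE 0.19), or 0.80 without the 3 arrays that stood apart. Of 15 neural genes 1 was higher and 3 lower (1 and 4 adjusted over the list alone, adjusted p = 0.174), with the neurofilament gene Nefl at -1.27 (SE 0.13), or -0.83 after quantile normalization. The neural list passed at adjusted p = 0.0214 without the 3 arrays that stood apart and at adjusted p = 0.0418 without Flk1+ array 4 alone. Of 30 basement membrane and matrix genes 3 were higher and 5 lower (4 and 8 adjusted over the list alone, adjusted p = 0.4). After quantile normalization the smooth muscle (adjusted p = 0.000186), Notch (adjusted p = 0.0456) and cardiac lists (adjusted p = 0.0118) passed towards Flk1+ cells.

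In all, 2352 features were called between the sorts at 84 h, 925 higher and 1427 lower in Flk1+ cells, and for 1644 the arrays of the 2 sorts did not overlap. Over all 17440 features tested, called or not, 3027 (17.4%) had no overlap, where chance gives 2.86%. From the deposited scale the split was 1447 higher and 1209 lower. Fitting only the 8 arrays compared gave 347 calls, and leaving out the 3 arrays that stood apart gave 1176. Single arrays moved the count as well, to 4550 without Flk1+ array 1, 1510 without array 2, 4206 without array 3 and 1159 without array 4, and to 1018, 1017 and 1116 without Flk1- arrays 1, 2 and 3. Of the 35 genes named here for 84 h 34 had no overlap between the sorts, the exception being Dkk1. Single arrays lay apart from the other 3 of their group for Wnt2, Notch1 and Nefl.

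**Figure D3:**
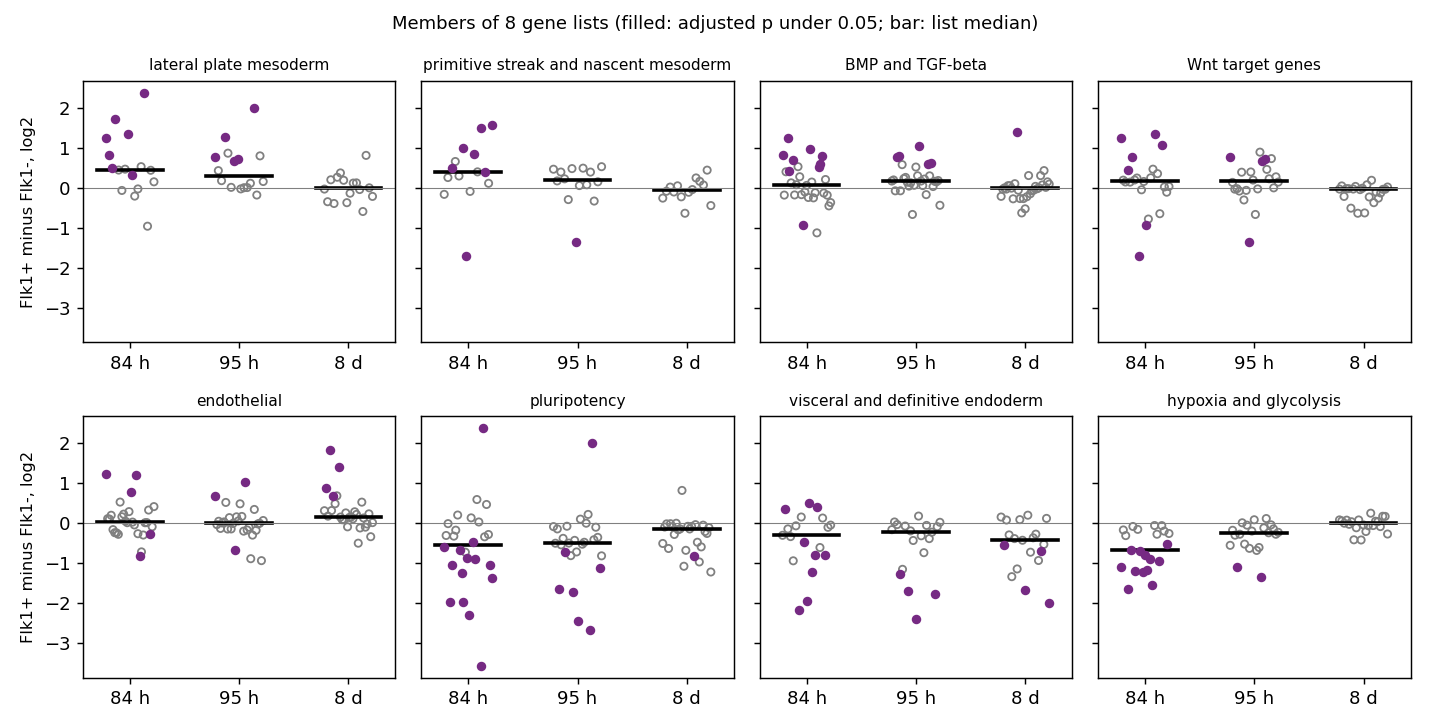
Flk1+ minus Flk1- log2 differences (axis of values) of the measured members of 8 lists at 84 h, 95 h and 8 d, with filled points for called genes, open points for genes not called and a bar at each list's median. Endoderm genes lie at medians of -0.30, -0.22 and -0.43 at the 3 times.

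At 95 h lateral mesoderm genes were higher in Flk1+ cells. Tbx3 was 1.99 (SE 0.18) and Hand1 1.27 (SE 0.23) higher in Flk1+ cells, and Prdm6 was 1.46 (SE 0.28) higher. Of 16 lateral plate mesoderm genes 5 were higher, 0 lower and 11 not called (8 and 0 adjusted over the list alone), with a median of 0.30 and adjusted p = 4.6e-12, or adjusted p = 0.000244 with an estimated correlation. Klhl6 rose by 2.12 (SE 0.20) and Ackr3, a chemokine receptor gene, by 1.74 (SE 0.25). Myl7, the atrial myosin light chain, rose by 1.44 (SE 0.25) and Fgf10 by 1.13 (SE 0.19). Of 29 BMP and TGF-beta genes 5 were higher, 0 lower and 24 not called (5 and 1 adjusted over the list alone), with a median of 0.17 and adjusted p = 1.2e-05, or adjusted p = 0.000733 with an estimated correlation. Bmp5 rose by 0.79 (SE 0.13) and the signal transducer gene Smad1 by 1.04 (SE 0.20), a call that ended when only the arrays compared were fitted and with the probe of the largest SD.

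Pluripotency and endoderm genes were lower in Flk1+ cells at 95 h. Sox2 was lower in Flk1+ cells at -2.66 (SE 0.37), Lefty1 at -2.44 (SE 0.17) and Klf2 at -1.71 (SE 0.20). Of 26 pluripotency genes 1 was higher, 6 lower and 19 not called (1 and 16 adjusted over the list alone), with a median of -0.49 and adjusted p = 1.94e-16, or adjusted p = 0.000109 with an estimated correlation. Foxa2 was lower at -2.39 (SE 0.20), Sox17 at -1.76 (SE 0.21), Epcam at -1.69 (SE 0.29) and Cdh1 at -1.88 (SE 0.34). Of 19 endoderm genes 0 were higher, 4 lower and 15 not called (0 and 7 adjusted over the list alone), with a median of -0.22 and adjusted p = 4.87e-12, or adjusted p = 0.000126 with an estimated correlation. Other low genes in Flk1+ cells were Igfbp3 at -2.18 (SE 0.23), Trh at -2.06 (SE 0.17) and the heat shock gene Hspb1 at -1.14 (SE 0.16). Of 21 hypoxia and glycolysis genes 0 were higher, 2 lower and 19 not called (0 and 5 adjusted over the list alone), with a median of -0.24 and adjusted p = 2.42e-06, or adjusted p = 0.0198 with an estimated correlation. The 2 were Pdk1 at -1.34 (SE 0.18) and Ddit4 at -1.09 (SE 0.23), of which Ddit4 lost its call when only the arrays compared were fitted and with array weights.

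Endothelial genes did not pass as a list at 95 h. Of 28 measured 2 were higher, 1 lower and 25 not called (4 and 3 adjusted over the list alone, adjusted p = 0.369). Nrp1 rose by 1.04 (SE 0.11), while Flt1, another VEGF receptor gene, was lower at -0.66 (SE 0.16, adjusted p = 0.0281). The Flt1 call ended when only the arrays compared were fitted, with array weights, with quantile normalization and without the 95 h arrays numbered 2. It also ended without Flk1+ array 1, 3 or 4 or Flk1- array 2, with differences from -0.66 to -0.53. Kit was lower at -1.46 (SE 0.22), the 1 called gene of 9 hemangioblast regulators (adjusted p = 0.0723). That list passed without Flk1+ array 2 (adjusted p = 0.0225), Flk1- array 1 (adjusted p = 0.0314) or Flk1- array 3 (adjusted p = 0.0178). Of 14 immediate early and heat shock genes 0 were higher and 2 lower at adjusted p = 0.00576, or adjusted p = 0.235 with an estimated correlation, and adjusted p = 0.0935 without Flk1+ array 4.

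At 95 h 354 features were called, 115 higher and 239 lower in Flk1+ cells, with no overlap of arrays for 313 (838 or 4.8% of all features) and for each of the 30 genes named. With the replicate number as a block within time the count was 545, and from only the 8 arrays compared it was 135. Without the 3 arrays of 84 h that stood apart it was 698, a change that comes through the pooled spread. Hand1 and Wnt2 lost their calls with array weights, and Fst and Msx1 without the 95 h arrays numbered 2. Single arrays lay apart from the other 3 of their group for Klhl6, Klf2, Epcam, Igfbp3 and Flt1.

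At 8 d endothelial genes formed the leading group on the Flk1+ side. Cdh5, which encodes the endothelial junction protein VE-cadherin, was 1.84 (SE 0.15) higher, Eng, a TGF-beta coreceptor, 1.39 (SE 0.22), Cd34 0.89 (SE 0.12) and the Notch ligand gene Dll4 0.67 (SE 0.13). Of 28 endothelial genes 4 were higher, 0 lower and 24 not called (9 and 0 adjusted over the list alone), with a median of 0.17 and adjusted p = 3.23e-17, or adjusted p = 0.000193 with an estimated correlation. Ctla2b rose by 2.49 (SE 0.28), Fermt3 by 1.76 (SE 0.21), Plek, pleckstrin, by 1.41 (SE 0.27), Myct1 by 1.29 (SE 0.28) and Adgrg1 by 1.07 (SE 0.22). Of 11 leukocyte and platelet genes 0 were called by limma over all arrays and 2 higher from only the arrays compared (1 and 0 adjusted over the list alone, adjusted p = 0.155). Of 9 hemangioblast regulators 1 was higher and 0 lower, with a median of 0.034 and adjusted p = 0.0158. This list gave adjusted p = 0.221 with an estimated correlation, adjusted p = 0.112 after quantile normalization, adjusted p = 0.0784 with the block within time and adjusted p = 0.0625 without the 3 arrays of 84 h that stood apart. Of 13 erythroid genes 0 were called by limma over all arrays and 2 lower from only the arrays compared (0 and 1 adjusted over the list alone), and the list passed towards Flk1- cells with a median of -0.062, at adjusted p = 0.0158 or adjusted p = 0.109 with an estimated correlation. Of 19 Notch genes 2 were higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.124), with Mfng at 0.82 (SE 0.16). The Notch list passed without Flk1+ array 1 (adjusted p = 0.00516). Leaving out 1 array ended the call of Adgrg1 (0.82 to 1.13) and of Myct1 (1.15 to 1.33) for each array but Flk1+ array 3. It ended that of Dll4 (0.55 to 0.69) for each but Flk1+ arrays 1 and 3. The call of Mfng (0.67 to 0.82) ended without Flk1+ array 2 or 4 or Flk1- array 1, 3 or 4. The call of Plek (1.28 to 1.41) ended without Flk1+ array 1, 2 or 4 or Flk1- array 3 or 4.

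Endoderm genes were the leading group on the Flk1- side at 8 d. Ttr, the thyroid hormone carrier, was lower in Flk1+ cells at -1.999 (SE 0.16), Foxa2 at -1.67 (SE 0.20), Mttp at -0.70 (SE 0.11) and the apolipoprotein gene Apoa1 at -0.53 (SE 0.10). Of 19 endoderm genes 0 were higher, 4 lower and 15 not called (0 and 11 adjusted over the list alone), with a median of -0.43 and adjusted p = 8.13e-31, or adjusted p = 3.05e-07 with an estimated correlation. F3, tissue factor, was lower at -1.75 (SE 0.37), the basement membrane collagen gene Col4a1 at -1.70 (SE 0.31), S100g at -1.46 (SE 0.24), Lgmn at -1.39 (SE 0.20), metallothionein Mt2 at -1.38 (SE 0.23) and Slc39a8 at -1.38 (SE 0.25). Of 26 pluripotency genes 0 were higher, 1 lower and 25 not called (1 and 6 adjusted over the list alone), with a median of -0.15 and adjusted p = 7.68e-11, or adjusted p = 0.000193 with an estimated correlation. The 1 was Otx2 at -0.81 (SE 0.15). Of 22 cardiac contractile genes 0 were higher, 2 lower and 20 not called (0 and 5 adjusted over the list alone), at adjusted p = 7.64e-06 or adjusted p = 0.071 with an estimated correlation. The 2 were Myl4 at -0.90 (SE 0.16) and Mybpc3 at -0.73 (SE 0.12). Of 30 basement membrane and matrix genes 0 were higher, 1 lower and 29 not called (0 and 4 adjusted over the list alone), with a median of -0.08 (-0.15 after quantile normalization) and adjusted p = 0.000104, or adjusted p = 0.026 with an estimated correlation. Without Flk1+ array 1 the calls of Col4a1 (-1.59), Myl4 (-0.82) and Slc39a8 (-1.29) ended, and without Flk1- array 4 those of Col4a1 (-1.55) and Otx2 (-0.78). Leaving out 1 array ended the call of F3 (-1.90 to -1.47) for each array but Flk1- array 2. The call of Apoa1 (-0.55 to -0.47) ended for each but Flk1- array 4.

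At 8 d 65 features were called, 26 higher and 39 lower in Flk1+ cells, with no overlap of arrays for 64 (2781 or 15.9% of all features). With the block within time the count was 139, after quantile normalization 218, from only the 8 arrays compared 952 and with array weights 2332. From only these arrays 9 endothelial genes were higher and 9 endoderm and 9 pluripotency genes lower. Without the 3 arrays of 84 h that stood apart it was 172. It fell to 37, 42 and 36 without Flk1+ arrays 1, 3 and 4, and to 40, 37 and 31 without Flk1- arrays 1, 3 and 4. Leaving out 1 array ended 13 of the 26 calls named here, as given with each gene. Hspb1 (-0.78, SE 0.16) lost its call with each array left out but Flk1- array 2, with differences from -0.825 to -0.70. Apoa1 and Hspb1 also lost theirs after quantile normalization and F3 with the replicate block.

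The ligand genes Wnt2 and Wnt5a were higher in Flk1+ cells at the first 2 times. Wnt2 was higher by 2.66 (SE 0.23, adjusted p = 1.61e-07) at 84 h, 1.86 (SE 0.23, adjusted p = 4.15e-05) at 95 h and 1.17 (SE 0.23, adjusted p = 0.0221) at 8 d, where arrays of the sorts overlapped and the call ended when only the arrays compared were fitted. Wnt5a, a ligand known for signalling without beta-catenin, was higher by 1.62 (SE 0.20, adjusted p = 1.53e-05) at 84 h and 0.86 (SE 0.20, adjusted p = 0.0213) at 95 h. The 95 h call of Wnt5a ended when only the arrays compared were fitted, with array weights, with quantile normalization and without the 95 h arrays numbered 2. It also ended without Flk1+ array 2 or 4 or Flk1- array 3 or 4 (0.72 to 0.84). At 8 d its difference was 0.15 and not called. The 8 d call of Wnt2 ended with 1 array left out (0.9997 to 1.20) for each array but Flk1+ array 2 and Flk1- array 1. Of 14 measured Wnt ligands and receptors 2 were higher and 0 lower at 84 h (2 and 1 adjusted over the list alone), with a median of 0.16 and adjusted p = 0.00918, or adjusted p = 0.117 with an estimated correlation. Without Flk1+ array 1 or array 3 this list gave adjusted p = 0.0535 and adjusted p = 0.0806. At 95 h 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.13 and adjusted p = 0.00309, or adjusted p = 0.0358 with an estimated correlation. At 8 d 1 was higher (adjusted p = 0.15), and the list passed at adjusted p = 0.0294 without Flk1+ array 2.

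Wnt target genes passed as a list towards Flk1+ cells at 84 h and 95 h and towards Flk1- cells at 8 d. At 84 h 5 of 22 were higher and 2 lower (7 and 2 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00852, or adjusted p = 0.0299 with an estimated correlation and adjusted p = 0.0595 without Flk1+ array 3. The higher members included Msx2 and Bmp4, also lateral plate genes, and Nkd1, an inhibitor of Dishevelled, at 1.06 (SE 0.21). Dkk1, a secreted Wnt inhibitor, was higher at 0.77 (SE 0.18), or 1.25 without the 3 arrays that stood apart. Its call ended from only the arrays compared and after quantile normalization. Fst, the activin antagonist and also a streak gene, was lower at -1.70 (SE 0.30) at 84 h and -1.35 (SE 0.30) at 95 h. At 84 h it was -1.07 without these 3 arrays, and its call ended from only the arrays compared. With this overlap the list is not separate evidence. At 95 h 3 of 22 were higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00438, or adjusted p = 0.0107 with an estimated correlation. Msx1 was higher by 0.68 (SE 0.16), a call that ended without Flk1+ array 1, 2 or 4 or Flk1- array 4 (0.60 to 0.66) and from only the arrays compared. Lef1, a nuclear partner of beta-catenin, at 0.89 (SE 0.25, adjusted p = 0.0829) and Nkd1 at 0.73 (adjusted p = 0.0818) were not called at 95 h. Lef1 passed from only the arrays compared (adjusted p = 0.0498), with array weights (adjusted p = 0.0106) and without the 3 arrays of 84 h that stood apart (adjusted p = 0.000361), and Nkd1 passed with the block within time at adjusted p = 0.000705. At 8 d 0 of 22 were called by limma over all arrays and 2 lower (Dkk1 and Msx2) from only the arrays compared. The list passed at adjusted p = 0.0158, or adjusted p = 0.026 with an estimated correlation, with a median of -0.04 and mean of -0.13.

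Other Wnt lists did not pass between the sorts. Of 37 intracellular components 3 were higher and 2 lower at 84 h (adjusted p = 0.655), 0 and 1 at 95 h (adjusted p = 0.369) and 0 and 0 at 8 d (adjusted p = 0.76). From only the arrays compared 1 and 1 were called at each of the first 2 times and 2 and 2 at 8 d. The corepressor gene Ctbp2 was lower at -1.19 (SE 0.17) at 84 h, or -0.78 without Flk1+ arrays 2 and 4, and at -0.75 (SE 0.17) at 95 h, a call that ended without Flk1+ array 1 (-0.67) or Flk1- array 3 (-0.69). Of 6 secreted inhibitors 2 were higher at 84 h, Dkk1 and Frzb, the latter at 1.00 (SE 0.19) with its call ended by fitting only the arrays compared. This list had a median of -0.06, a mean of 0.14 and adjusted p = 0.456, which became adjusted p = 0.0368 after quantile normalization. At 95 h and 8 d 0 of 6 were called by limma over all arrays (adjusted p = 0.424 and adjusted p = 0.574), and from only the arrays compared 1, Dkk1, was lower at 8 d.

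**Figure D4:**
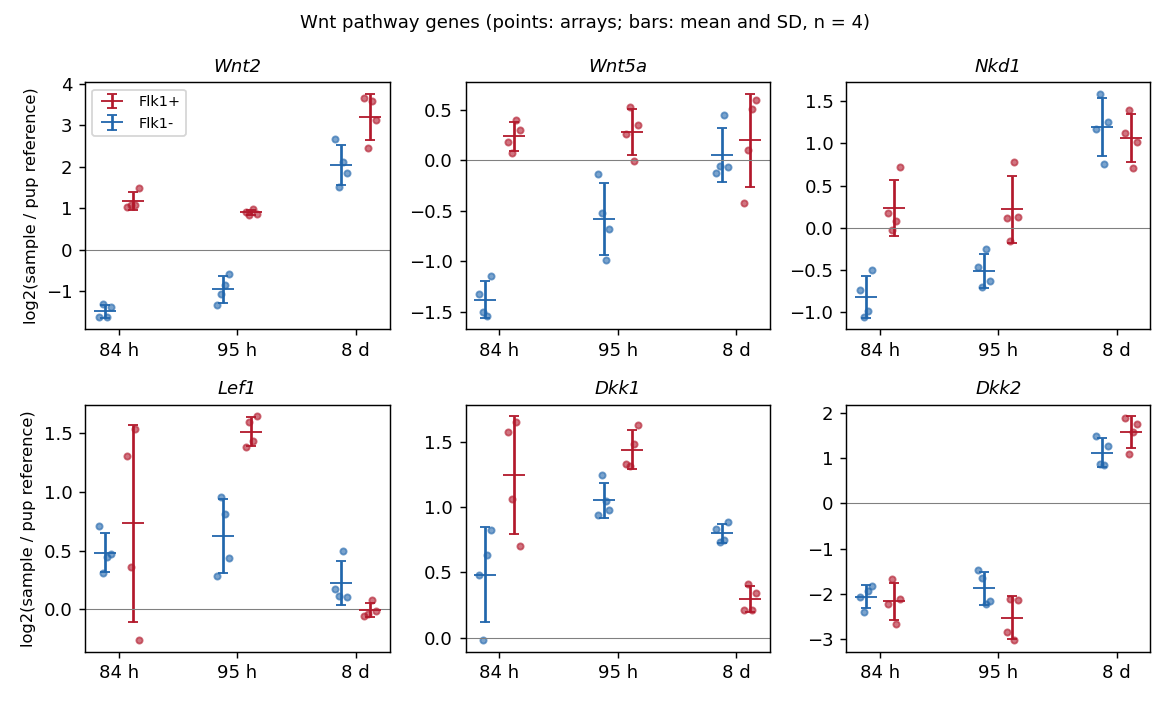
Log2 ratios to the pup reference (vertical axes) of Wnt2, Wnt5a, Nkd1, Lef1, Dkk1 and Dkk2 at 84 h, 95 h and 8 d, 1 point per array, red for Flk1+ and blue for Flk1-, bars for mean and SD of 4 arrays. Wnt2 in Flk1+ cells has means of 1.17 at 84 h, 0.90 at 95 h and 3.21 at 8 d.

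From 84 h to 95 h calls within Flk1+ cells varied with the arrays kept, and 9 of 12 named held without the 3 that stood apart. Cavin2 rose by 2.20 (SE 0.37), Podxl by 1.30 (SE 0.23), the laminin gene Lama4 by 1.12 (SE 0.16), the growth factor gene Vegfc by 1.02 (SE 0.16), the BMP antagonist gene Nog by 0.88 (SE 0.17) and Tnni3 by 0.73 (SE 0.11). Lhx1 changed by -1.57 (SE 0.27), Foxa2 by -1.16 (SE 0.20) and the Nodal coreceptor gene Tdgf1 by -1.13 (SE 0.24). Rps3a1, a ribosomal protein gene, rose by 1.94 (SE 0.59), Cct2, a chaperonin gene, by 1.91 (SE 0.52) and Lef1 by 0.78 (SE 0.25). Without these 3 arrays they gave 0.15, 0.51 and 0.09 and were not called. The call of Cct2 ended without 84 h array 2 (1.44) or 4 (1.45), that of Rps3a1 without these (1.30 and 1.40) or 95 h array 1, 2 or 3 (1.90, 1.98 and 1.95). The call of Lef1 ended without these 2 of 84 h (0.66 and 0.45) or any of 95 h (0.82, 0.75, 0.81 and 0.74). Podxl was 0.68 and Tdgf1 -0.69 without these, Tdgf1 -0.42 and Lhx1 -0.97 after quantile normalization, and Tnni3 0.31 after it. The cell cycle list rose (7 of 34 higher, 1 lower, 11 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0304), with adjusted p = 0.561 with an estimated correlation and a median of -0.045 without the 3 arrays that stood apart. It also lost its call without 95 h array 1 (adjusted p = 0.0825) or 3 (adjusted p = 0.06) or 84 h array 2 (0.257, adjusted p = 0.117) or 4 (0.255, adjusted p = 0.0673). Array 2 of 95 h lay apart from the other 3 for Lhx1. Of 3451 features called 1947 were higher and 1504 lower at 95 h, or 1648 and 2018 from the deposited scale. Fitting only the 8 arrays compared gave 0 calls by limma (3020 at an unadjusted p under 0.05), so each of the 12 genes named lost its call there, and 951 were called without the 3 arrays that stood apart. The count became 2158 without 95 h array 2, and 5358, 1895 and 1637 without 84 h arrays 1, 2 and 4.

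Within Flk1- cells genes of smooth muscle and endoderm rose from 84 h to 95 h. Of 21 smooth muscle and fibroblast genes 4 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.38 (0.21 after quantile normalization), at adjusted p = 1.7e-07 or adjusted p = 0.0427 with an estimated correlation. Postn rose by 1.35 (SE 0.19) and the smooth muscle actin gene Acta2 by 0.83 (SE 0.11). Of 19 endoderm genes 3 were higher and 0 lower (6 and 1 adjusted over the list alone), at adjusted p = 9.66e-06 or adjusted p = 0.00236 with an estimated correlation, with Sox17 at 0.86 (SE 0.21) and the tight junction gene Cldn6 at 0.68 (SE 0.16). Hspb1 rose by 1.10 (SE 0.16), Fgf10 by 0.91 (SE 0.19), Wnt5a by 0.80 (SE 0.20), the cardiac troponin gene Tnnt2 by 0.72 (SE 0.14) and Nrp1 by 0.65 (SE 0.11, or 1.19 from the probe with the largest SD). Lhx1 changed by -1.25 (SE 0.27, or -0.77 without all 5 arrays that stood apart), Dnmt3b by -0.99 (SE 0.14), Pdk1 by -0.89 (SE 0.18) and Otx2 by -0.86 (SE 0.15). Quantile normalization ended the calls of Postn (0.17), Dnmt3b (-0.46), Lhx1, Otx2, Sox17, Tnnt2 and Wnt5a, and fitting only the arrays compared those of Cldn6, Fgf10, Lhx1, Nrp1, Otx2, Pdk1, Sox17 and Wnt5a. Leaving out 1 array ended the call of Fgf10 for 84 h arrays 2 (0.83) and 3 (0.91), that of Pdk1 for 84 h array 2 (-0.86) and 95 h array 2 (-0.76). It ended that of Lhx1 for 84 h arrays 3 (-1.29) and 4 (-1.06) and 95 h array 2 (-0.96). It ended that of Cldn6 (0.5003 to 0.70) for each but 95 h arrays 3 and 4, that of Sox17 (0.72 to 0.88) for each but 84 h array 4 and 95 h array 3, and that of Wnt5a (0.65 to 0.88) for each but 95 h array 3. Of 286 features called 184 were higher and 102 lower at 95 h, against 70 from only the arrays compared and 668 without the 3 arrays of 84 h that stood apart. The count was 449 and 136 without 95 h arrays 1 and 2, and 149, 105, 93 and 182 without 84 h arrays 1, 2, 3 and 4.

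Other lists passed in Flk1- cells over this step only with the preset correlation. Of 28 endothelial genes 2 were higher and 0 lower (6 and 2 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.00728, or adjusted p = 0.109 with an estimated correlation. Of 30 basement membrane and matrix genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.16 at adjusted p = 0.00728 or adjusted p = 0.109 with an estimated correlation. Both gave adjusted p = 0.0219 after quantile normalization and adjusted p = 0.0535 without all 5 arrays that stood apart. Of 27 VEGF, angiopoietin, PDGF and FGF genes 2 were higher and 0 lower (2 and 1 adjusted over the list alone), with a median of 0.16 at adjusted p = 0.0162. This became adjusted p = 0.0825 with an estimated correlation and adjusted p = 0.069 without 95 h array 4. Lists of lateral plate (median 0.25) and cardiac genes (0.14), upwards, and of pluripotency (-0.12) and hypoxia genes (-0.17), downwards, passed at adjusted p = 0.0162 to adjusted p = 0.0206. With an estimated correlation they gave adjusted p = 0.109, adjusted p = 0.227, adjusted p = 0.174 and adjusted p = 0.225. Quantile normalization ended the first 3 calls (adjusted p = 0.0817, adjusted p = 0.382 and adjusted p = 0.616), and the probe with the largest SD the last 2 (adjusted p = 0.146 and adjusted p = 0.0703). Leaving out 95 h array 3 ended the first (adjusted p = 0.0511), 95 h array 1, 95 h array 2 or 84 h array 4 the third (adjusted p = 0.0993, adjusted p = 0.0623 and adjusted p = 0.132) and 95 h array 4 or 84 h array 4 the last (adjusted p = 0.161 and adjusted p = 0.0694).

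From 95 h to 8 d both sorts gained mesenchymal and matrix genes and lost streak genes. Postn rose by 5.87 in Flk1+ and 5.54 in Flk1- cells (SE 0.19), Acta2 by 3.69 and 3.58 (SE 0.11), Snai2 by 3.58 and 3.46 (SE 0.21), and Tbx4 by 3.87 and 2.88 (SE 0.33). Goosecoid (Gsc) changed by -3.00 and -2.83 (SE 0.18), Mesp1 by -2.98 and -2.75 (SE 0.28), Tdgf1 by -2.54 and -2.44 (SE 0.24) and Car2 by -2.95 and -2.58 (SE 0.25). Pdgfrb, the PDGF receptor gene of mural cells, rose by 2.49 and 2.76 (SE 0.16), the matrix gene Tgfbi by 3.09 and 2.83 (SE 0.22), the immediate early gene Egr1 by 2.44 and 1.86 (SE 0.20) and embryonic globin Hbb-y by 2.15 and 2.22 (SE 0.14). In Flk1+ and Flk1- cells 0 of 14 streak genes were higher and 9 lower (0 higher, 11 and 9 lower adjusted over the list alone), with medians of -1.13 and -0.78, at adjusted p = 0.0011 and adjusted p = 0.00108 with an estimated correlation. Of 30 basement membrane and matrix genes 15 and 20 were higher and 0 lower (18 and 22 higher, 2 and 0 lower adjusted over the list alone), at adjusted p = 0.00286 and adjusted p = 0.000136 with an estimated correlation. Of 21 smooth muscle and fibroblast genes 13 were higher in each sort and 0 and 1 lower (13 higher, 2 and 1 lower adjusted over the list alone), with medians of 0.89 (0.50 after quantile normalization) and 1.08, at adjusted p = 0.00396 and adjusted p = 0.00111 with an estimated correlation. Of 26 pluripotency genes 1 was higher in each sort and 11 and 15 were lower (1 higher, 12 and 20 lower adjusted over the list alone), at adjusted p = 0.00396 and adjusted p = 0.000136 with an estimated correlation. Single arrays lay apart from the other 3 of their group for Tbx4, Hbb-y, Pdgfrb, Tgfbi and Mesp1.

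Endothelial genes rose in Flk1+ cells over the same step. Of 28 measured 13 were higher and 0 lower (15 and 1 adjusted over the list alone), with a median of 0.43 (0.28 after quantile normalization) and adjusted p = 1.74e-08, or adjusted p = 0.00396 with an estimated correlation. Cdh5 rose by 2.92 (SE 0.15), Ctla2b by 3.72 (SE 0.28), Angpt2 by 2.66 (SE 0.24), Col18a1 by 3.11 (SE 0.23) and Kit by 1.501 (SE 0.22). In Flk1- cells 8 of 28 endothelial genes were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.17, at adjusted p = 0.00155 or adjusted p = 0.121 with an estimated correlation. After quantile normalization 7 were higher and 5 lower, with a median of 0.013 and adjusted p = 0.0296. Flk1- cells gained Ackr3 by 3.42 (SE 0.25), Nrp1 by 2.45 (SE 0.11, or 3.80 from the probe with the largest SD) and Ttr by 1.87 (SE 0.16), while Trh changed by -2.79 (SE 0.17) and Lefty1 by -2.50 (SE 0.17). Tbx3 changed by -2.67 (SE 0.18) in Flk1+ cells. Of 16 lateral plate genes 7 were higher and 0 lower in Flk1- cells (8 and 0 adjusted over the list alone), at adjusted p = 1.06e-06 or adjusted p = 0.00361 with an estimated correlation. Of 29 BMP and TGF-beta genes 11 were higher and 1 lower in these cells (13 and 1 adjusted over the list alone), at adjusted p = 3.62e-05 or adjusted p = 0.0022 with an estimated correlation.

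Wnt pathway genes moved in both directions from 95 h to 8 d. Wnt2 rose by 2.31 in Flk1+ and 3.00 in Flk1- cells (SE 0.23), and the secreted inhibitor gene Dkk2 by 4.11 and 2.99 (SE 0.25). Lef1 changed by -1.52 (SE 0.25) and Dkk1 by -1.15 (SE 0.18) in Flk1+ cells, and Nkd1 rose by 1.70 (SE 0.21) in Flk1- cells. Of 22 Wnt target genes 5 were higher and 7 lower in Flk1+ cells (5 and 10 adjusted over the list alone, adjusted p = 0.141). Of 6 secreted inhibitors 3 were higher and 2 lower in Flk1+ cells (3 and 2 adjusted over the list alone), with a median of 0.46, at adjusted p = 0.0196 or adjusted p = 0.223 with an estimated correlation. After quantile normalization 2 were higher and 2 lower, with a median of 0.055 and adjusted p = 0.159, and without the 3 arrays of 84 h that stood apart the list gave adjusted p = 0.102. Of these 6 genes 3 were higher and 0 lower in Flk1- cells (3 and 0 adjusted over the list alone), at adjusted p = 0.000925 or adjusted p = 0.0196 with an estimated correlation. In all, 3861 features were called in Flk1+ cells, 2238 higher and 1623 lower at 8 d, or 2304 and 2697 after quantile normalization. In Flk1- cells 3080 were called, 1723 higher and 1357 lower. Arrays of the 2 times had no overlap for 3586 and 2764 of these features. Without the 3 arrays of 84 h that stood apart the counts were 5864 and 5087. The 2 sorts shared 1303 higher and 706 lower features, with no chance level known, as 1 fit gave both.

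The difference between the sorts itself changed from 95 h to 8 d for 93 features, 61 towards Flk1+ and 32 towards Flk1- cells, or 57 and 59 after quantile normalization. Cdh5 gained 1.97 (SE 0.22) and Adgrg1 2.23 (SE 0.32) towards Flk1+ cells, Cd34 0.92 (SE 0.17) and Mfng 1.12 (SE 0.22), of which Cd34 lost its call after quantile normalization. Klf2 at 2.53 (SE 0.28), Igfbp3 at 2.39 (SE 0.33), Lefty1 at 2.36 (SE 0.24) and Pdk1 at 1.59 (SE 0.26), low in Flk1+ cells at 95 h, moved the same way. Tbx3 at -2.58 (SE 0.25), Myl7 at -2.15 (SE 0.35), Ttr at -2.02 (SE 0.22), Hand1 at -1.66 (SE 0.33), Fgf10 at -1.61 (SE 0.27), Myl4 at -1.39 (SE 0.23) and Nrp1 at -0.75 (SE 0.15) moved towards Flk1- cells. The call of Hand1 ended without Flk1+ array 1 (-1.62) or 2 (-1.57) of 8 d and that of Nrp1 without the latter (-0.73) and from the probe with the largest SD. Single arrays lay apart from the other 3 of their group for Adgrg1 (Flk1+ array 1 of 95 h) and Klf2 (that array and Flk1- array 1 of 8 d). The endothelial list moved towards Flk1+ cells (2 of 28 higher, 1 lower, 8 and 1 adjusted over the list alone, median 0.18, adjusted p = 9.46e-05, or adjusted p = 0.0455 with an estimated correlation). Lateral plate mesoderm (0 and 2 of 16, 0 and 7 adjusted over the list alone, median -0.43, adjusted p = 1.04e-09), Wnt target genes (0 and 0 of 22, 0 and 6 adjusted over the list alone, median -0.19, adjusted p = 9.46e-05) and BMP and TGF-beta genes (0 and 0 of 29, 1 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.000382) moved the other way. With an estimated correlation these 3 gave adjusted p = 0.00209, adjusted p = 0.00209 and adjusted p = 0.00379. The count was 173 with the block within time, 161 from only the arrays compared and 314 without the 3 arrays of 84 h that stood apart. It was 47, 50 and 57 without Flk1+ arrays 1, 2 and 3 of 8 d, and 59, 61 and 51 without Flk1- arrays 2, 3 and 4 of 8 d.

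From 84 h to 95 h the difference between the sorts changed for 1 feature in limma's fit, against 2686 at an unadjusted p under 0.05. This unnamed probe, chosen after its values were seen, differed between the sorts at -0.84 at 84 h and 0.22 at 95 h, a change of 1.05 (SE 0.15, adjusted p = 0.00792). The count was 0 from only the arrays compared and after quantile normalization, 5 with the block within time, and 31 without the 3 arrays that stood apart. It was 6, 4 and 6 without Flk1+ arrays 1, 2 and 4 of 95 h, 2, 2 and 3 without Flk1- arrays 1, 3 and 4 of 95 h, 4, 11, 3 and 3 without Flk1+ arrays 1, 2, 3 and 4 of 84 h, and 2 without Flk1- array 4 of 84 h. Cell cycle, streak and hypoxia lists passed at adjusted p = 0.00127, adjusted p = 0.0173 and adjusted p = 0.0173, and with an estimated correlation at adjusted p = 0.728, adjusted p = 0.56 and adjusted p = 0.56. The streak list lost its call without Flk1- array 4 of 95 h (adjusted p = 0.133), Flk1+ array 3 of 84 h (adjusted p = 0.114) or Flk1- array 2 of 84 h (adjusted p = 0.0662). The hypoxia list lost its call without the first 2 of these (adjusted p = 0.133 and adjusted p = 0.0507) or Flk1- array 4 of 84 h (adjusted p = 0.0707). Quantile normalization ended the streak call (adjusted p = 0.284), and leaving out the 3 arrays that stood apart those of the cell cycle (adjusted p = 0.326) and hypoxia lists (adjusted p = 0.119).

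Calls at 84 h and 95 h, which share no arrays, had 81 higher and 177 lower features in common. For 84 h and 8 d these numbers were 5 and 21, and for 95 h and 8 d 6 and 18. All times share 1 fit and its spread per feature, so no chance level is known. Counts with other settings are given below. Without Flk1+ arrays 1, 3 and 4 of 8 d the 26 shared by 84 h and 8 d became 15, 14 and 12. The 24 shared by 95 h and 8 d became 12, 12 and 10. Without Flk1- arrays 3 and 4 of 8 d the first became 16 and 12. Without Flk1- arrays 1, 3 and 4 of 8 d the second became 15, 14 and 11. Across features, which are not independent replicates, the Flk1+ minus Flk1- differences of 84 h and 95 h correlated at r = 0.317 (rho = 0.186), those of 84 h and 8 d at r = 0.0544 (rho = -0.0179) and those of 95 h and 8 d at r = 0.0963 (rho = -0.0290). Kdr and Wnt2 (towards Flk1+ cells) and Foxa2 (towards Flk1- cells) were among the genes called between the sorts at all 3 times.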

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

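2 tests were chosen after the result was seen. They are that of the spread per array for the 84 h arrays that stood apart and that of the pooled spread for 8 d.

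Among 324 groups of 4 arrays, 20 (6.2%) held a highest or lowest array whose gap to the nearest other exceeded Dixon's critical value for the group's range, where chance gives about 1 in 20. The ratios of gap to range for the mean correlation with the own group were 0.870 for Flk1- array 4 of 84 h (0.88 against a median of 0.93 of the others) and 0.848 for Flk1+ array 4 of 8 d (0.92 against 0.94). At 84 h the ratio was 0.896 for Wnt2 in Flk1+ array 4 (1.495 against a median of 1.07 of the others), 0.903 for Notch1 in Flk1- array 4 (-0.06 against -0.79) and 0.856 for Nefl in Flk1+ array 2 (-1.71, lowest other -2.01). In Flk1+ cells of 95 h it was 0.90 for Klf2 in array 1 (-1.53 against -2.10), 0.878 for Pdgfrb in array 1 (-1.83 against -1.34) and 0.911 for Adgrg1 in array 1 (-2.71 against -2.18). In array 2 of that group it was 0.840 for Epcam (-0.78 against -1.14), 0.861 for Igfbp3 (-2.38 against -2.80), 0.947 for Lhx1 (1.28 against 2.07), 0.918 for Hbb-y (-0.48 against -0.08) and 0.965 for Mesp1 (3.30 against 3.71). In Flk1- cells of 95 h it was 0.913 for Kdr (-1.30 against -0.998) and 0.910 for Klhl6 (-0.99 against -0.27) in array 1 and 0.932 for Flt1 (0.74 against 0.24) in array 2. At 8 d it was 0.868 for Kdr in Flk1+ array 4 (1.89 against 1.46), 0.888 for Tbx4 in Flk1+ array 2 (1.37 against 2.63), 0.888 for Tgfbi in Flk1+ array 1 (1.41 against 0.72) and 0.879 for Klf2 in Flk1- array 1 (-0.27 against -0.84).

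The Flk1+ minus Flk1- difference changed between times, by the interaction test, for 1 feature from 84 h to 95 h and for 93 features from 95 h to 8 d. Among named genes the later change was positive for Klf2 (2.53), Igfbp3 (2.39), Lefty1 (2.36), Adgrg1 (2.23), Rpl39l (2.14), Ctla2b (2.13), Cdh5 (1.97), Tpd52 (1.81), Fermt3 (1.76), Trh (1.69), Pdk1 (1.59), Col18a1 (1.497), Mfng (1.12), Cldn6 (0.98), Cd34 (0.92) and Tnni3 (0.78). It was negative for Tbx3 (-2.58), Myl7 (-2.15), Ttr (-2.02), Ackr3 (-1.80), Hand1 (-1.66), Fgf10 (-1.61), Klhl6 (-1.41), Myl4 (-1.39), Gata3 (-1.38) and Nrp1 (-0.75).

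The first pattern is that Flk1+ arrays 2 and 4 of 84 h stood apart from arrays 1 and 3. Admixture of Flk1- cells alone was excluded, but not with another cause. Of 2180 genes deviating by 1 or more, 2121 (97.3%, 95% interval 96.5 to 97.9, counting error only) overshot the Flk1- mean or moved away. A wider spread of values alone was excluded too, since after quantile normalization the highest correlation with arrays 1 and 3 was 0.679, against 0.839 with each other and 0.932 between arrays 1 and 3. The deviations of the 2 arrays from the mean of the others correlated at 0.737 across features. Cells of another type stayed open, with a highest median deviation among 7 cell type lists of 0.45 for leukocyte and platelet genes and values of 0.29 for smooth muscle, 0.27 for erythroid, 0.20 for cardiac, 0.18 for neural, 0.03 for endoderm and -0.014 for pluripotency genes. No biological explanation besides a mixture of cells was tested.

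The second pattern is that the fit of all arrays called fewer genes at 8 d than at the earlier times, while fits of only the arrays compared called most at 8 d (347, 135 and 952). The estimated SD of true differences was 0.32 at 84 h, 0.13 at 95 h and 0.16 at 8 d. The last was 1.28 times that at 95 h (1.03 to 1.51 with 1 array left out). Against 84 h smaller differences stayed open, and against 95 h too, as a bias from pairing was not tested. The spread pooled with the wider arrays of 84 h and 95 h is a candidate explanation, since the 8 d arrays alone gave more calls. Time in culture, which the design names, stays open as untested.

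The third pattern is the lower level of hypoxia and glycolysis genes in Flk1+ cells at 84 h, set against the 3 arrays that stood apart. Without them the median was -0.377 (-0.67 to -0.33 over 2000 bootstrap draws), 20 of 21 genes lay below 0 and the list test gave an unadjusted camera p of 1.99e-08 in limma. The bounds written before the result were above -0.2 if these arrays were the cause and below -0.4 if they were not, so the value lay between them and the question stayed open. A difference in oxygen or metabolism between the sorts was not tested.

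Other splits of the same arrays bear on each count. At 84 h no other of 35 splits reached the real 2352 (1 split, the real one, gave as many). The highest other, 2224, set Flk1+ array 1 with Flk1- arrays 1, 2 and 3 against the rest, which points to a structure of the samples. At 95 h 2 of 35 splits gave as many as the real 354, the highest other being 417, so chance was not excluded over all splits. That split sets Flk1+ arrays 1 and 2 with Flk1- arrays 2 and 4, and among the 8 splits that part all 4 pairs, as the real one does, the highest other was 8. At 8 d 1 of 35 splits, the real one, gave as many as 65 (highest other 1, and 0 among splits that part all pairs). For Flk1+ cells at 95 h against 84 h it was 1 of 35 (3451, highest other 1838, with 84 h arrays 2 and 4 and 95 h arrays 1 and 2 together, again a structure of the samples). The share was also 1 of 35 splits each for Flk1+ cells at 8 d against 95 h (3861, highest other 0), Flk1- cells at 95 h against 84 h (286, highest other 1) and Flk1- cells at 8 d against 95 h (3080, highest other 2). For the interactions, 38 of 100 splits gave as many as the 1 feature from 84 h to 95 h (highest other 810), so chance was not excluded. Only 1 of 100, the real split, gave as many as the 93 from 95 h to 8 d (highest other 58).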

How the results depend on the processing

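The settings without arrays that stood apart were chosen after seeing the data, and the other alternatives were planned. Of 540 gene results, the same direction and side of the threshold held for 537 with a robust fit, 527 as deposited, 520 with the probe of the largest SD, 477 after quantile normalization, 450 with array weights and 408 from only the arrays compared. Those from the arrays compared included 125 that lost and 7 that gained a call. Of 198 list results 157 held with an estimated correlation, and 41 lost their call. With 1 array left out 3981 of 4472 gene results and 1870 of 1936 list results held. Kdr between the sorts was called in each setting run. The missing-value filters changed nothing, since no value was missing. The number of arrays limits precision, and signal over background was not given in the sources used here. The cause was not tested for any value below, except that a fold minimum can only lower a count.

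At 84 h equal replicate numbers did not pair the samples, with correlations of 0.340, -0.128, 0.313 and 0.526 and a highest correlation between different numbers of 0.365. The plain replicate block gave 2604 calls between the sorts at 84 h, 336 at 95 h and 69 at 8 d, 3631 and 3979 for the 2 steps in Flk1+ cells, 314 and 3197 in Flk1- cells, and 1 and 87 for the interactions. With the block within time the counts were 4386 at 84 h, 545 at 95 h and 139 at 8 d, and 5 and 173 for the interactions, with 402 calls shared by 84 h and 95 h, 56 by 84 h and 8 d and 45 by 95 h and 8 d. Other calls of genes and list tests printed here that a block changed were Wnt5a in Flk1- cells at 95 h against 84 h, Cldn6 and Col18a1 in the later interaction, Msx1 at 84 h and the BMP and VEGF lists at 84 h. Counts of list members moved too, as for cell cycle at 84 h (10 lower) and erythroid genes at 8 d (1 lower) with the plain block. Within time they moved for hypoxia at 95 h (5 lower) and pluripotency at 8 d (1 higher, 3 lower).

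In the order 84 h, 95 h and 8 d between the sorts, then the earlier and later step in Flk1+ and in Flk1- cells, then the earlier and later interaction, the main counts were 2352, 354, 65, 3451, 3861, 286, 3080, 1 and 93. With a fold minimum they were 382, 117, 26, 557, 777, 47, 656, 1 and 53. After quantile normalization 84 h gave 1304, 8 d 218, the earlier Flk1+ step 1625 and the earlier interaction 0, with 49 calls shared by 84 h and 8 d and 41 by 95 h and 8 d. From only the arrays compared 84 h gave 347, 95 h 135, 8 d 952, the earlier Flk1+ step 0, the earlier Flk1- step 70 and the interactions 0 and 161 (limma, with 3020 at an unadjusted p under 0.05 for the earlier Flk1+ step), and 78 calls were shared by 84 h and 95 h and 50 by 84 h and 8 d.

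With array weights the counts were 3625 at 84 h, 2332 at 8 d, 804 and 6059 in Flk1+ cells, 2156 and 6692 in Flk1- cells, and 46 and 288 for the interactions, with 241 calls shared by 84 h and 8 d and 80 by 95 h and 8 d. Without Flk1+ arrays 2 and 4 of 84 h they were 1419, 648 and 148 between the sorts, 882 for the earlier Flk1+ step, 935 and 4919 in Flk1- cells, and 34 and 260 for the interactions, with 41 calls shared by 84 h and 8 d and 44 by 95 h and 8 d. Without Flk1- array 4 of 84 h as well they were 1176, 698 and 172, 951 and 5864, 668 and 5087, and 31 and 314, with 43 and 49 shared. Without the 95 h arrays numbered 2 the earlier interaction gave 2. Without all 5 arrays the counts were 840 at 95 h and 265 at 8 d, 1433 and 7181, 917 and 6078, and 109 and 440, with 470 calls shared by 84 h and 95 h, 55 by 84 h and 8 d and 60 by 95 h and 8 d.

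With 1 array left out the counts ranged from 1017 to 4550 at 84 h, 286 to 364 at 95 h and 31 to 54 at 8 d. They ranged from 1637 to 5358 and 2873 to 3687 in Flk1+ cells, from 93 to 449 and 2308 to 2992 in Flk1- cells, and from 1 to 11 and 47 to 101 for the interactions. Shared calls ranged from 205 to 296 for 84 h and 95 h, 12 to 38 for 84 h and 8 d and 10 to 28 for 95 h and 8 d. The Wnt ligand list ranged in its median from 0.136 to 0.207 at 84 h and 0.0111 to 0.0671 at 8 d, and the Wnt target list from 0.164 to 0.241 at 84 h. Kdr ranged from 1.63 to 2.22 at 84 h, 2.85 to 2.97 at 95 h and 1.79 to 1.94 at 8 d.

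Directions reversed for Serpinf1 at 84 h (0.38) and the cardiac list at 84 h (0.17) after quantile normalization, and for Pgk1 in the earlier Flk1+ step without all 5 arrays (-0.028). The cell cycle list reversed at 84 h without Flk1+ arrays 2 and 4 (0.025), in the earlier Flk1+ step without these (-0.045), without 3 arrays (-0.045) and without all 5 (-0.0062). Its median in the earlier interaction, 0.35, was 0.037 without Flk1+ arrays 2 and 4 (adjusted p = 0.996). The median of the Wnt ligand list at 84 h, 0.16, lost its call with an estimated correlation (adjusted p = 0.117), and at 95 h, 0.13, without all 5 arrays (adjusted p = 0.0622). Secreted Wnt inhibitors at 84 h gained one after quantile normalization (0.33, adjusted p = 0.0368). The pup list median was -2.02 with the probe of the largest SD.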

Other observations

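The families of genes below and the tests on them were chosen after the results were seen, so the epithelial and mesenchymal families are not independent evidence of their direction.

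Genes of epithelial junctions and keratins were lower in Flk1+ cells at all 3 times. Of 23 measured, 16 were lower and 1 higher at 84 h (median -0.999), 13 lower and 0 higher at 95 h (median -0.67) and 6 lower and 0 higher at 8 d (median -0.36). Camera tests with an estimated correlation, adjusted over the 6 families tried, gave adjusted p = 3.08e-06, adjusted p = 5.12e-09 and adjusted p = 2.14e-09. The membrane protease gene St14 was at -1.66, -1.46 and -0.91 at the 3 times, and the tight junction gene Cldn4 at -1.19, -1.44 and -1.26. The 1 higher gene was Krt8 at 84 h (0.39), which was not called after quantile normalization. Medians stayed negative from the deposited scale (-0.95, -0.66 and -0.37) and after quantile normalization (-0.73, -0.62 and -0.47). At 8 d the count of lower genes was 10 after quantile normalization and 11 without the 3 arrays of 84 h that stood apart.

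Mesenchymal genes went the other way at the first 2 times. Of 26 measured, 11 were higher and 0 lower at 84 h (median 0.22, adjusted p = 0.00223 with an estimated correlation) and 6 and 0 at 95 h (median 0.14, adjusted p = 0.00108), and at 8 d 0 were called by limma (median 0.034, adjusted p = 0.884). Fibronectin (Fn1) was at 1.36 and 0.88 and N-cadherin (Cdh2) at 0.98 and 0.55 at 84 h and 95 h. Hoxb1 was higher in Flk1+ cells by 1.87 (SE 0.17) at 84 h and 1.08 at 95 h, and was the 1 called gene of 14 measured in the Hox clusters at these times (adjusted p = 0.145 and adjusted p = 0.304 for the family).

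Ribosomal protein, proteasome and chaperonin genes did not pass as families at 84 h. Of 49 cytosolic ribosomal protein genes 20 were lower and 0 higher (median -0.39, adjusted p = 0.0814 with an estimated correlation), and 3 were lower without the 3 arrays of 84 h that stood apart (median -0.17). Of 34 proteasome genes 10 were lower and 0 higher (median -0.69, adjusted p = 0.145), and 3 were lower without these arrays (median -0.20). Of 7 CCT chaperonin genes 1 was higher and 3 lower (median -0.79, adjusted p = 0.41). Without these arrays 0 were higher and 1 lower (median -0.10).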
